A study of Homo sapiens with 6 samples.

How the data were processed

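RNA was extracted from U2OS cells 48 hours after siRNA transfection, and strand-specific libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols. Such a kit captures polyadenylated RNA. Groups and replicate numbers were taken from the sample titles, with 3 siCtrl and 3 siNUDT5 libraries. The deposited table gives TPM per gene symbol for the 6 libraries, each summing to the same total, with no gene identifiers and no repeated symbol. The submitters' processing notes name STAR 2.7.3a, DESeq2 1.22.1 and the build hg19, without saying what each was used for. How TPM were computed, from which annotation, whether strand was used in counting and how reads shared between gene copies were treated are not given in the sources used here. No coordinates are printed, because the annotation at hand is of another build. Its gene names, the gene order in RefSeq and the 3' UTR sequences of GENCODE 29 were used by symbol.

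Because TPM are normalized values, no count model was run. Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with lmFit and eBayes with a trend, siNUDT5 minus siCtrl, two-sided, over the 12236 genes with a mean of at least 1 TPM over the 6 libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold change means an absolute log2 change of at least 1. Log2 changes are on the log2(TPM + 1) scale, which understates the change of low genes. Means and SDs are of TPM over the 3 libraries of a group. The exact permutation test of NUDT5 was run in scipy 1.17.1 with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

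Of 39 gene lists, 38 with at least 5 tested members were tested with limma's camera, with the preset inter-gene correlation of 0.01 and adjustment over the 38 lists. Camera with an estimated correlation and fry, a rotation test of whether a list's members move on balance one way, were run beside it. Of 1025 list entries 1022 matched a symbol of the table. The lists, the tests, the filter, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes NUDT5, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out clone-based names, LINC, MIR, SNOR and RNU symbols. It adds up to 4 members past the threshold, by size of change, from each list that passes camera or has at least 3 members past the threshold. Symbols are printed as the table gives them, some in older form.

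Relative depth came from genes under 0.3 TPM in siCtrl 1, as the ratio of a gene's values in another library and siCtrl 1. After division by one factor per library, 72.0% to 81.5% of these ratios lay within 0.1% of a ratio of whole numbers up to 5, where at most 0.890% would by chance. Whole reads per gene were not recovered, since what a read is worth depends on gene length. The fit was tested on simulated data for siNUDT5 minus siCtrl over 12236 genes. Of 100 genes changed by 0.5 on the log2 scale 47% were recovered and of 100 genes changed by 1, 99%, with 17 false calls and no wrong sign. The simulated noise was drawn independently for each gene and library, so shifts shared by many genes of a library were not simulated.

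For the closing observations, each 7-base word was searched in the longest annotated 3' UTR of each gene. A 3' UTR of at least 50 bases was found for 11915 of the 12236 tested genes (97.4%), 464 of them through another symbol. Log2 changes were adjusted for 3' UTR length, GC content and mean expression by linear regression, clipped at the outer 0.5% on either side, and compared between genes with and without each of 16354 words held by at least 30 genes, as a z value. In simulated data over 11915 genes, a word whose carriers were lowered by 0.1 ranked 1 of all words. To test a word on genes that did not pick it, the searched genes were parted at random into 5957 and 5958, the lowest and highest word were picked in one part and tested in the other, and both parts picked the same words. Distinct words are those that share no run of 5 bases with the picked word.

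The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, leaving out mitochondrial genes, other prior variances, the replicate number as a block, and leaving out each library in turn. Leaving out genes that carry certain 3' UTR words was added after the data were seen.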

Results

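The series measured polyadenylated RNA in U2OS cells, a human osteosarcoma line, 48 hours after transfection with a non-targeting control siRNA (siCtrl) or with an siRNA against NUDT5 (siNUDT5). NUDT5 is a NUDIX hydrolase that cleaves ADP-ribose. There were 3 libraries in each of the 2 groups, 6 in all, and the comparison asks how lowering NUDT5 changes gene expression in these cells. Chromatin accessibility, which the series' design also names, was not analysed here. The values were TPM, a transcript abundance scaled for transcript length and library total, for 19977 gene symbols, of which 3074 were listed at 0 in all 6 libraries. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

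TPM keeps no total depth, but low values moved in steps of whole reads and gave the relative depth. Taking siCtrl 1 as 100%, siCtrl 2 had 64.1% of its depth, siCtrl 3 had 112% and siNUDT5 1, 2 and 3 had 89.4%, 118% and 105%. A single read in a low gene was worth about 0.050 TPM in siCtrl 1. siCtrl 2 also stood apart in expression. It differed from siCtrl 1 by a median of 0.296 and from siCtrl 3 by 0.227 on the log2(TPM + 1) scale, whereas the other 4 within-group pairs differed by 0.0967 to 0.134. The first principal component separated the groups and held 55.0% of the variance, and the second held 30.1% and set siCtrl 1 and siCtrl 2 farthest apart. No 2 libraries of the same group held an identical value above 0 for any gene, and pairs between groups were not checked.

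NUDT5 mRNA was strongly reduced in every siNUDT5 library. It stood at 46.2, 49.0 and 52.0 TPM in siCtrl 1 to 3 and at 3.04, 2.74 and 2.67 TPM in siNUDT5 1 to 3. The means were 49.1 ± 2.90 TPM and 2.82 ± 0.198 TPM (SD, n = 3 each), so that 5.74% of the control level remained. An exact two-sided permutation test of the TPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. In the limma fit across all genes the log2 change was -3.71 (standard error 0.0982, adjusted p = 1.32e-06). CDC123, the next protein-coding gene beside NUDT5 in RefSeq's order, was also lower, at 343 ± 28.9 TPM against 200.3 ± 4.61 TPM (SD, n = 3 each). Its log2 change was -0.77 with adjusted p = 0.00119. It was looked up after the data were seen. Of the other 9 neighbours within 5 places on either side, 1 passed, CCDC3, with a log2 change of 0.34 and adjusted p = 0.0367.

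**Figure D1:**
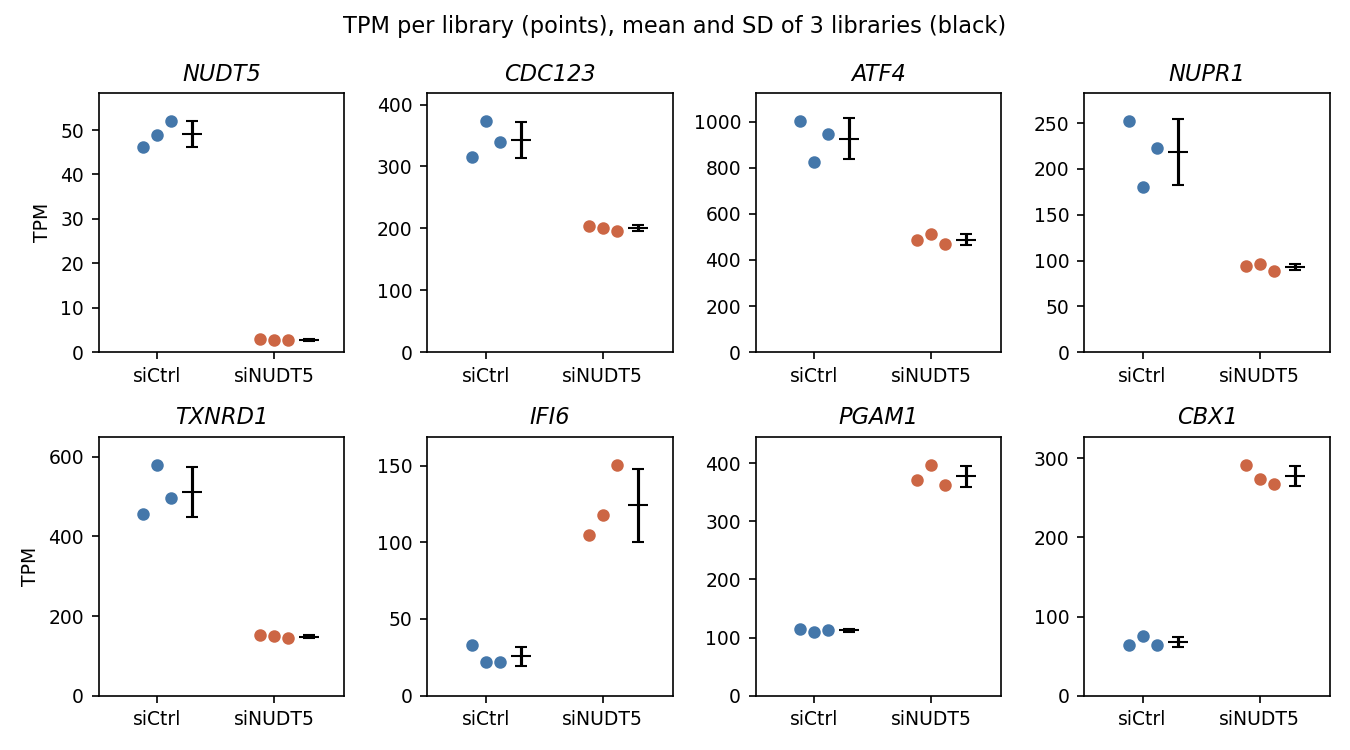
TPM of 8 genes in each library (points, 3 siCtrl in blue and 3 siNUDT5 in orange), with the mean and SD of each group in black and every axis starting at 0. The siNUDT5 libraries lay below all siCtrl libraries for NUDT5, CDC123, ATF4, NUPR1 and TXNRD1, and above them for IFI6, PGAM1 and CBX1.

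Beyond the target, interferon-stimulated IFI6, the chemokine CCL5 and the heterochromatin protein gene CBX1 were among the largest rises. MAPK6, which encodes an atypical MAP kinase, and TXNRD1, the cytosolic thioredoxin reductase, had the largest falls after NUDT5. In all, 1970 of 12236 tested genes passed an adjusted p of 0.05 (limma on log2(TPM + 1), two-sided, Benjamini-Hochberg), 1334 higher and 636 lower in siNUDT5. Of these, 157 changed at least 2-fold, 105 upward and 52 downward. The median absolute log2 change of the genes that passed was 0.55. The 3 values of each group did not overlap in 4558 genes, 37.3% of those tested, where chance gives 10%. Median-ratio scaling left 1040 higher and 895 lower, and quantile normalization 1018 higher and 965 lower. The median of all log2 changes was 0.05 without such scaling. The count was 3804 without siCtrl 2, 868 without siCtrl 3, and 843, 775 and 764 without siNUDT5 1, 2 and 3.

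**Figure D2:**
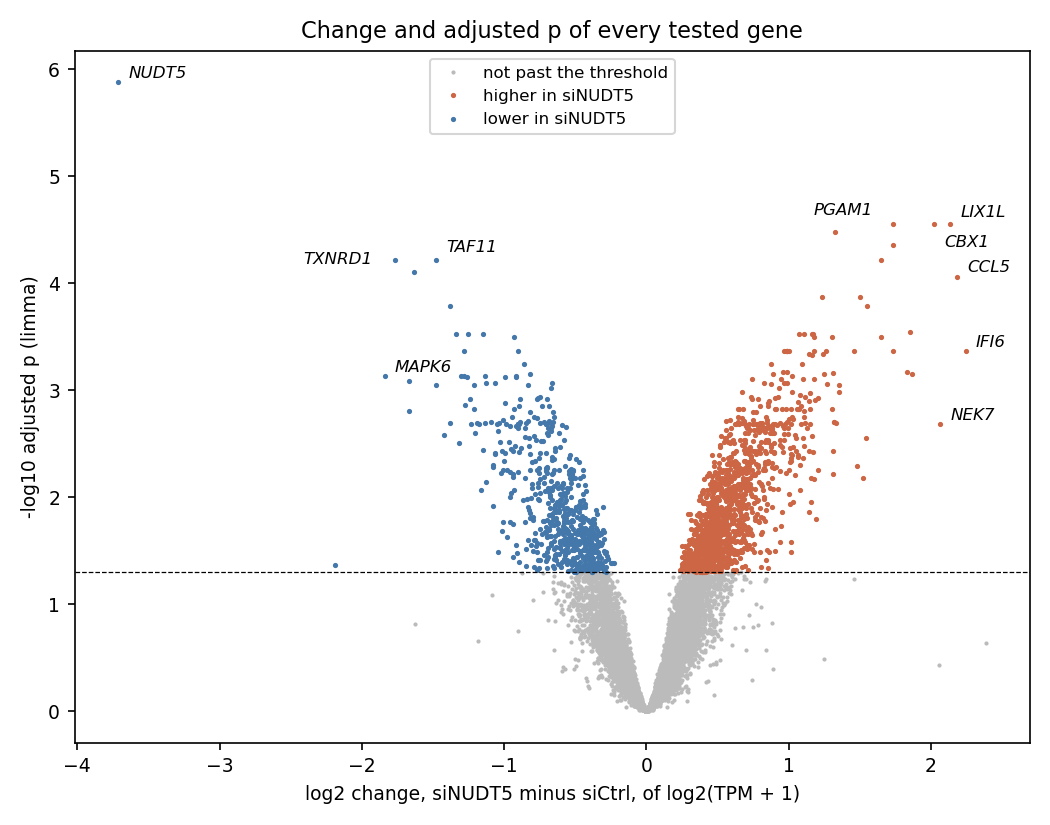
Each point is one of the 12236 tested genes, with its log2 change (siNUDT5 minus siCtrl, on the log2(TPM + 1) scale) on the horizontal axis and -log10 of its limma adjusted p on the vertical axis, and the dashed line at an adjusted p of 0.05. NUDT5 lies alone at the upper left at -3.71, and IFI6, CCL5, LIX1L, NEK7 and CBX1 lie farthest to the right among the named genes.

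The 12 largest rises were led by IFI6, which rose from 25.6 ± 6.31 to 124 ± 23.8 TPM (SD, n = 3 each), a log2 change of 2.24 with adjusted p = 0.000427. CCL5 was listed at 0 in siCtrl 1 and siCtrl 3 and stood at 0.167 TPM in siCtrl 2. It stood at 4.07, 3.36 and 3.96 TPM in siNUDT5 1 to 3, with adjusted p = 8.65e-05. LIX1L rose from 8.30 ± 0.731 to 39.7 ± 0.895 TPM (log2 change 2.13). CBX1, which encodes heterochromatin protein HP1 beta, rose from 68.0 ± 6.32 to 278 ± 12.4 TPM (2.02). The others were the kinase gene NEK7 (log2 change 2.06), the sphingosine-1-phosphate phosphatase gene SGPP1 (1.87), the scavenger receptor gene COLEC12 (1.85), ARL6IP1 (1.83), the glucose transporter gene SLC2A3 (1.74), the semaphorin gene SEMA6B (1.74), the glycolytic enzyme gene PGAM1 (1.73) and the p53 target ZMAT3 (1.65). All 12 had an adjusted p of at most 0.00208, the value of NEK7. In 6 of these 12 genes (LIX1L, NEK7, CBX1, SGPP1, ARL6IP1 and ZMAT3) the annotated 3' UTR held the word GATTAAC, which 6.21% of the searched genes held. The word was picked on these same log2 changes, so this excess is no separate evidence. PGAM1, CBX1 and SLC2A3 have near-identical copies elsewhere in the genome, and how the authors counted shared reads is not given in the sources used here.

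The 12 largest falls after NUDT5 began with MAPK6, from 132 ± 37.3 to 35.4 ± 1.54 TPM (SD, n = 3 each), a log2 change of -1.84 with adjusted p = 0.000736. TXNRD1 fell from 511 ± 62.9 to 149 ± 3.56 TPM (-1.77), and TAF11, which encodes a TFIID subunit, from 149 ± 7.99 to 52.97 ± 2.20 TPM (-1.48). The others were C12orf39 (log2 change -1.67), C9orf84 (-1.67), the carbonic anhydrase gene CA2 (-1.63), FAM217B (-1.48), the fatty acid elongase gene ELOVL7 (-1.42), the phosphatase inhibitor gene PPP1R14C (-1.38), SCEL (-1.38), the transcription factor gene IKZF4 (-1.34) and the olfactory receptor gene OR51B4 (-1.31). Their highest adjusted p was 0.00310, that of OR51B4. A 3' UTR was searched for 11 of these 12 genes, and in 8 of them it held AAGACTT or AGACTTA, words that 22.4% of the searched genes held. These words too were picked on the same log2 changes.

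Among 38 gene lists fixed before the data were examined, the ATF4 and amino acid response genes, called the integrated stress response here, had the lowest p. Of 29 tested members 15 fell, 1 rose and 13 did not pass, and adjusted over the list alone 19 fell and 1 rose. Without siCtrl 2, 20 fell, and 7 to 9 fell without siCtrl 3 or any 1 siNUDT5 library. ATF4, the transcription factor at the centre of the response, fell from 925 ± 89.3 to 488 ± 22.8 TPM (SD, n = 3 each), a log2 change of -0.92 with adjusted p = 0.000748. NUPR1 (log2 change -1.21), the cystine transporter gene SLC7A11 (-1.13) and the glutathione-degrading enzyme gene CHAC1 (-1.02) fell further. PSAT1, an enzyme of serine synthesis, went the other way, from 47.5 ± 7.89 to 131 ± 9.12 TPM (1.46), while the serine synthesis genes PHGDH (-0.50) and PSPH (-0.48), chosen after their values were seen, fell. The members' median log2 change was -0.33, and limma's camera test against all other genes with a preset inter-gene correlation of 0.01 gave adjusted p = 1.97e-09. The adjusted p was 0.459 with an estimated correlation.

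Interferon-stimulated genes rose as a list. Of 31 tested members 14 rose, 1 fell and 16 did not pass, and adjusted over the list alone 15 rose and 3 fell. Of these 31, 17 rose and 3 fell without siCtrl 2, and 9 rose without siNUDT5 1. Besides IFI6, ISG15 rose from 13.5 ± 5.02 to 39.3 ± 7.38 TPM (log2 change 1.53), IFI27 from 0.379 ± 0.330 to 2.84 ± 0.939 TPM (1.48) and OASL from 1.10 ± 0.544 to 3.66 ± 1.01 TPM (1.16, SD and n = 3 each). GBP1 was the member that fell, by 0.67 on the log2 scale. HLA-B, chosen after its value was seen, had a log2 change of -0.10 and was not past the threshold. The median was 0.30 and camera gave adjusted p = 0.0123, and the adjusted p was 0.459 with an estimated correlation. The interferon genes IFNB1 and IFNL1 were listed at 0 in all 6 libraries.

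Unfolded protein response genes, a list of endoplasmic reticulum chaperones and other XBP1 or ATF6 targets, rose and NRF2-regulated antioxidant genes fell as lists. In the unfolded protein response list 9 of 22 tested members rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell. MANF rose from 155 ± 4.81 to 248 ± 3.78 TPM (SD, n = 3 each, log2 change 0.67), EDEM1, a factor of endoplasmic reticulum degradation, changed by 0.65 and SDF2L1 by 0.64, while HERPUD1, another such factor, fell from 94.8 ± 4.33 to 52.9 ± 2.76 TPM (-0.83). HERPUD1 held AAGACTT and AGACTTA in its 3' UTR. Camera gave adjusted p = 0.0350 for the list, and the adjusted p was 0.589 with an estimated correlation. The call was lost without siCtrl 1 (0.0595), without siCtrl 3 (0.0594) and without a trend (0.0536), with medians of 0.25, 0.24 and 0.26 against 0.26 with all libraries, and 4 or 5 genes rose without siCtrl 3 or any 1 siNUDT5 library. Of 20 NRF2 targets 3 fell and none rose, and adjusted over the list alone 5 fell and 1 rose. Without siCtrl 2, 8 fell and 2 rose. The 3 were TXNRD1, SLC7A11, which is also in the integrated stress response list, and the glutathione synthesis gene GCLM (-0.70). GCLM held AAGACTT and AGACTTA in its 3' UTR. Camera gave adjusted p = 0.00777, and the adjusted p was 0.589 with an estimated correlation.

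Glycolysis and immediate early genes also rose as lists. Of 21 glycolysis genes 6 rose and none fell, and adjusted over the list alone 8 rose. SLC2A3 and PGAM1 changed most, followed by the enolase gene ENO2 (log2 change 0.57) and the hexokinase gene HK1 (0.48). Camera gave adjusted p = 0.0153 with all libraries, with a median of 0.16 (quartiles 0.03 and 0.30), and the adjusted p was 0.650 with an estimated correlation. Camera gave 0.162 without siCtrl 2, where 8 rose and the median was 0.09 (quartiles -0.03 and 0.28). It gave 0.113 without genes carrying the 3' UTR words AAGACTT, AGACTTA or GATTAAC, an alternative chosen after seeing the data. There 19 members were tested and the median was 0.14 (quartiles 0.01 and 0.30). The 2 members left out held AAGACTT or AGACTTA, the words common among the largest falls, and neither held GATTAAC. SLC2A3, which rose, was 1 of them. Of 21 immediate early genes 10 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell. KLF2 changed by 0.94, FOS by 0.91, IER3 by 0.81 and EGR2 by 0.75 on the log2 scale, while MYC, chosen after its value was seen, fell by 0.35. Camera gave adjusted p = 0.0361 with all libraries, with a median of 0.32 (quartiles 0.03 and 0.49), and the adjusted p was 0.650 with an estimated correlation. Camera gave 0.0903 without siCtrl 2, though 12 rose and the median was 0.37 (quartiles 0.03 and 0.51), and 0.0526 without siCtrl 3 with a median of 0.34. It gave 0.175 at a mean of at least 5 TPM, with 18 members and a median of 0.30, and 0.186 without the word-carrying genes, with 15 members and a median of 0.31 (quartiles -0.13 and 0.63). None of the 10 immediate early genes that rose was found to hold GATTAAC. Without siCtrl 3 or any 1 siNUDT5 library 4 or 5 rose and none fell.

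Homologous recombination genes, cytosolic ribosomal protein genes and mitochondrially encoded transcripts passed camera as lower than other genes, with few members past the threshold. By fry, which tests whether the members of a list move on balance one way, their adjusted p was 0.303, 0.415 and 0.285 in this order, none past the threshold. Fry compares members with no change, not with other genes, while the median of all genes was 0.05. Among 26 homologous recombination genes 1, the strand-annealing gene RAD52, fell from 8.42 ± 0.342 to 4.97 ± 0.712 TPM (SD, n = 3 each, log2 change -0.66), and no other member passed, over all genes or adjusted over the list alone. Without siCtrl 1, 4 fell, and without siCtrl 2, 2 fell and 1 rose. Their median was -0.15, camera gave adjusted p = 0.00405, and the adjusted p was 0.650 with an estimated correlation. Among 74 ribosomal protein genes RPS20 fell (-0.27) and no other passed, and none did adjusted over the list alone. Their median was -0.09, camera gave adjusted p = 0.000179, and the adjusted p was 0.650 with an estimated correlation. Without siCtrl 2, 21 of them fell, none did without any other single library, and camera gave 0.0557 without siCtrl 1 and 0.0735 without siNUDT5 1, with a median of -0.05 in each. None of 13 mitochondrial transcripts passed on its own, also adjusted over the list alone. Their median was -0.17, camera gave adjusted p = 0.00993, and the adjusted p was 0.650 with an estimated correlation. Without siCtrl 2, 7 of them fell and the median was -0.27, and camera gave 0.0557 without siCtrl 1 and 0.0524 without siNUDT5 2, with medians of -0.14 and -0.10. Quantile normalization kept both directions but gave adjusted p = 0.202 for ribosomal proteins (median -0.04) and 0.289 for mitochondrial transcripts (-0.12). The libraries held 11.8 ± 0.464% of their TPM in mitochondrial genes in siCtrl and 10.8 ± 1.28% in siNUDT5 (SD, n = 3 each), so the group difference was within the spread.

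Of 20 NF-kappaB target genes 2 fell and none rose, both over all genes and adjusted over the list alone. They were TRAF1 (log2 change -1.28) and the feedback inhibitor gene TNFAIP3 (-0.47), and both carried AAGACTT in the 3' UTR. Without siCtrl 2, 5 fell and 2 rose. Camera gave adjusted p = 0.0457 with all libraries and 0.0811, 0.0933, 0.0988 and 0.0687 without siCtrl 1, siCtrl 2, siNUDT5 1 and siNUDT5 3. It gave 0.0576 without a filter, 0.0787 at a mean of at least 5 TPM, 0.0634 with median-ratio scaling, 0.0887 with quantile normalization or the replicate block, and 0.464 without the word-carrying genes, with 13 members and a median of -0.04 against -0.08 in all 20. By fry the adjusted p was 0.0514, and the adjusted p was 0.589 with an estimated correlation.

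**Figure D3:**
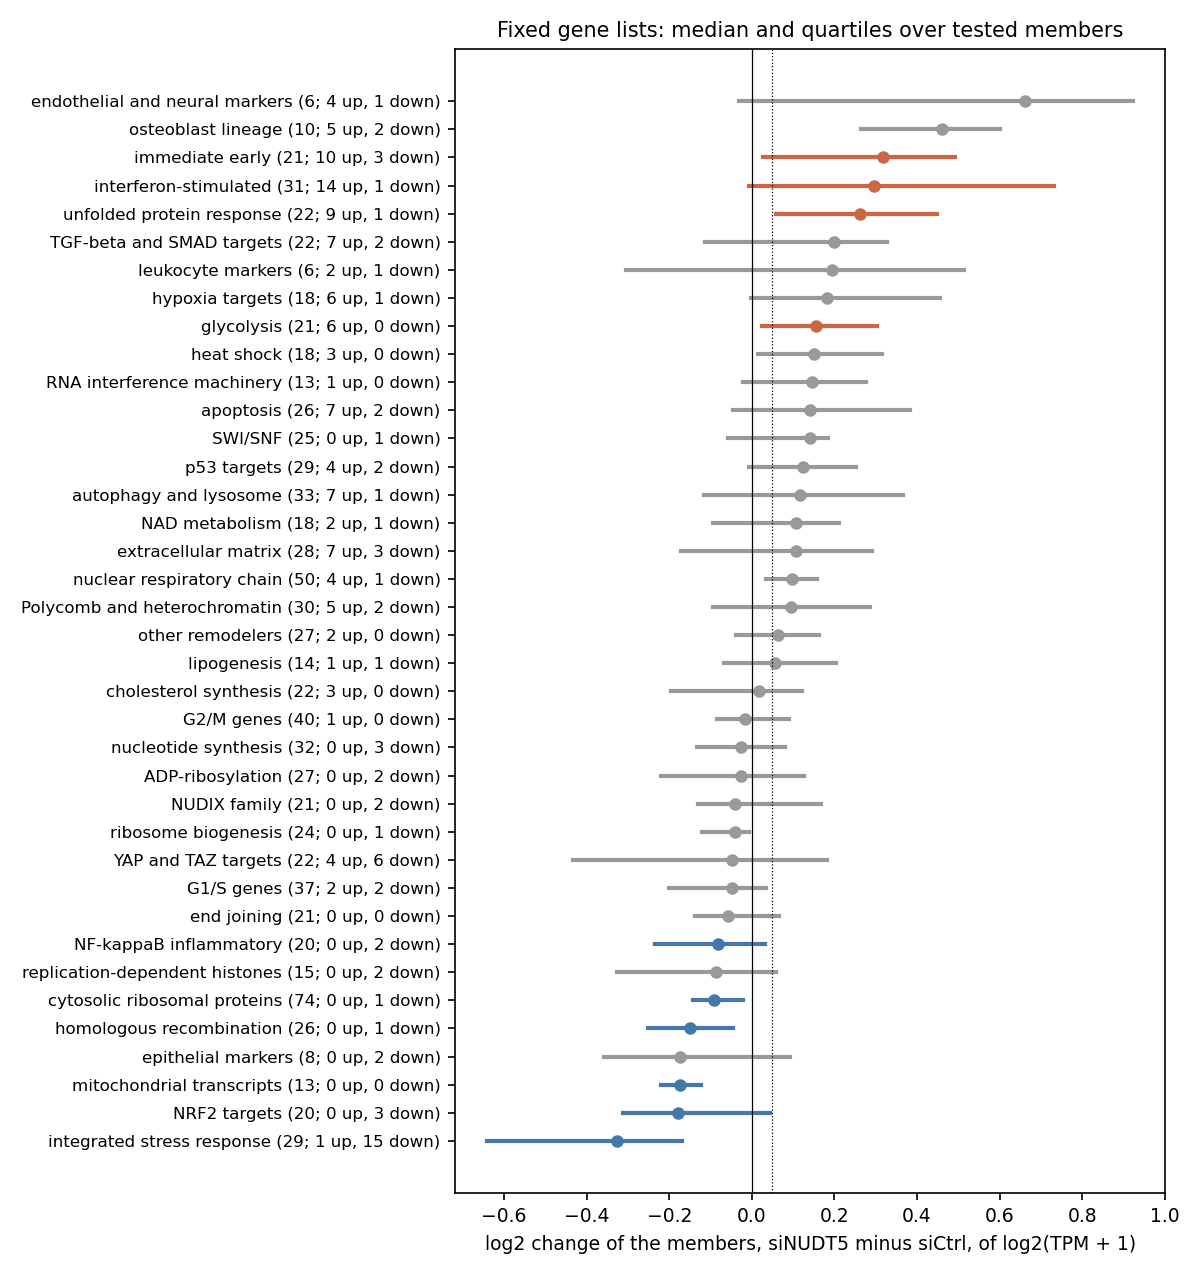
Median (point) and quartiles (bar) of the members' log2 changes (siNUDT5 minus siCtrl, log2(TPM + 1) scale) for each of 38 fixed gene lists, with the number of tested members and of members past the threshold beside each name. Lists past camera's adjusted p of 0.05 with the preset correlation are orange (higher) or blue (lower), the solid line marks 0 and the dotted line the median of all tested genes, and the integrated stress response has the lowest median at -0.33.

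The other 28 lists did not pass camera. Of 27 ADP-ribosylation genes 2 fell, PARP16 (log2 change -0.71) and the ADP-ribose hydrolase gene OARD1 (-0.47), and camera gave adjusted p = 0.151. Of 21 other NUDIX hydrolases 2 fell, DCP2 (-0.95) and NUDT19 (-0.62), with camera adjusted p = 0.364. In NAD metabolism NADSYN1 (0.46) and NNMT (0.33) rose and NMNAT1 (-0.38) fell among 18 genes, with camera adjusted p = 0.876. These counts were the same adjusted over the list alone. Without siCtrl 2 they became 4 rises and 4 falls, 3 rises and 3 falls, and 4 rises and 1 fall in the order given. Without siCtrl 3 or any 1 siNUDT5 library no NAD metabolism gene passed, 1 ADP-ribosylation gene fell without siCtrl 3 or siNUDT5 3, and 1 and 0 NUDIX genes fell without siNUDT5 2 and siNUDT5 3. PARP16, OARD1, DCP2 and NUDT19 fall outside the rule for named genes and were chosen after their values were seen. Of the 2 ADP-ribosylation genes that fell 1 held AAGACTT or AGACTTA in the 3' UTR, as did 1 of the 2 NUDIX genes.

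For the chromatin question in the design text, 1 of 25 SWI/SNF genes, ARID1A, fell (-0.30), and none did adjusted over the list alone, with camera adjusted p = 0.492. Without siCtrl 2, 3 rose and 1 fell, and none fell without any other single library. ARID1A held AAGACTT or AGACTTA in its 3' UTR. Of 30 Polycomb and heterochromatin genes 5 rose and 2 fell, and 9 rose and 4 fell adjusted over the list alone, with camera adjusted p = 0.443. Besides CBX1 they included DNMT3A (0.53), JARID2 (0.45) and CBX5 (0.39). Without siCtrl 2, 12 rose and 4 fell, and 1 or 2 rose without siCtrl 3 or any 1 siNUDT5 library. None of 21 end joining genes passed, over all genes or adjusted over the list alone, with camera adjusted p = 0.243, while 2 rose and 3 fell without siCtrl 2. Of 29 p53 targets 4 rose, ZMAT3, the death receptor gene TNFRSF10B (0.83) and C12orf5 (0.45) among them, and 2 fell, GADD45A (-0.45) among them. Adjusted over the list alone 5 rose and 2 fell, and camera gave adjusted p = 0.211. ZMAT3 and C12orf5 held GATTAAC in the 3' UTR, and without the word-carrying genes 2 of 22 members rose and 2 fell. Without siCtrl 2, 9 rose and 2 fell, and without siCtrl 3 or any 1 siNUDT5 library 2 rose and 1 fell. Fry, unlike camera, passed the p53 (adjusted p = 0.0253), SWI/SNF (0.0345) and Polycomb (0.0454) lists, each as higher. Fry compares members with no change and not with other genes, and the median of all genes was 0.05. The 3 medians were 0.12, 0.14 and 0.09, and 0.07, 0.09 and 0.04 with median-ratio scaling, where fry was not run. In the G1/S list CCNE1 (0.75) and PCNA (0.38) rose and CDC25A (-0.35) and SLBP (-0.33) fell among 37 genes, with the same counts adjusted over the list alone and camera adjusted p = 0.0572, which was 0.0390 without siNUDT5 2. It also passed with median-ratio scaling (0.0239) and quantile normalization (0.0313), each with 6 falls, without a filter (0.0478), at a mean of at least 5 TPM (0.0465) and without mitochondrial genes (0.0435). Without siCtrl 1 or siCtrl 2, 4 of the 37 fell, and none did without siCtrl 3 or any 1 siNUDT5 library.

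Several lists held both rises and falls with all libraries and did not pass camera. Of 22 YAP and TAZ targets 6 fell and 4 rose, with CYR61 down from 755 ± 35.0 to 395 ± 15.8 TPM (SD, n = 3 each, log2 change -0.93), AXL at -0.67, LATS2 at 0.95 and CRIM1 at 0.68. Adjusted over the list alone 7 fell and 5 rose, and camera gave adjusted p = 0.129, or 0.0317 without the word-carrying genes. LATS2 and CRIM1 held GATTAAC in the 3' UTR, and AXL held AAGACTT and AGACTTA. Without the word-carrying genes 5 of 12 members fell and 2 rose. Without siNUDT5 3, 5 fell and 2 rose, and with the replicate block 3 fell and 2 rose. Among 28 extracellular matrix genes 7 rose and 3 fell, with THBS1 at 0.96, MMP14 at 0.84, FBN1 at 0.67 and LUM at -0.72, and adjusted over the list alone 9 rose and 4 fell (camera adjusted p = 0.443). Without siCtrl 2, 9 rose and 7 fell. In the osteoblast lineage list, which also holds ATF4, 5 of 10 tested genes rose and 2 fell, with BMP4 at 0.86, MSX2 at 0.70 and SPP1 at -0.90. Adjusted over the list alone 6 rose and 2 fell, and camera gave adjusted p = 0.170. Hypoxia targets had 6 rises and 1 fall among 18, led by NDRG1 from 47.6 ± 2.56 to 104 ± 2.85 TPM (1.11), and 8 rises and 2 falls adjusted over the list alone. Their camera adjusted p was 0.151 with all libraries and 0.0234 without siCtrl 2, where 10 rose and 1 fell. Autophagy and lysosome genes had 7 rises and 1 fall among 33, led by WIPI1 (1.06), and 8 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.358), and 9 rises and 5 falls without siCtrl 2. The apoptosis list had 7 rises and 2 falls among 26, led by BCL2A1 (1.15), and 7 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.281). Without siCtrl 3 or any 1 siNUDT5 library the rises numbered 1 to 3 for hypoxia (also 3 without siCtrl 1), 2 for osteoblast, 4 for extracellular matrix, 3 to 5 for autophagy and 3 or 4 for apoptosis. Without siCtrl 3 and siNUDT5 1, 2 and 3 the falls numbered 2, 0, 1 and 0 for extracellular matrix, 1, 0, 2 and 0 for apoptosis and 0 in each for hypoxia. Fry passed the osteoblast (adjusted p = 0.0177) and apoptosis (0.0180) lists as higher.

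Markers of other cell types were summed per library. Epithelial markers summed to 887 ± 88.2 TPM in siCtrl and 728 ± 40.8 TPM in siNUDT5 (SD, n = 3 each), nearly all of it KRT18 and KRT8, and neither of these genes passed the test (adjusted p = 0.0579 and 0.142, limma). EPCAM fell from 9.89 ± 2.83 to 5.39 ± 0.30 TPM (log2 change -0.74, adjusted p = 0.0271) and KRT7 from 4.35 ± 0.536 to 2.73 ± 0.608 TPM (-0.53, adjusted p = 0.0476). Without siCtrl 2, 4 epithelial markers fell, and none did without siCtrl 3 or any 1 siNUDT5 library. Their camera adjusted p was 0.102 with all libraries, 0.0279 without siCtrl 2 and 0.0455 with all libraries and no filter, where 18 members were tested. Leukocyte markers summed to 31.0 ± 0.977 and 31.5 ± 1.08 TPM, with LCP1 lower (log2 change -0.93) and CD68 higher (1.01). Endothelial and neural markers summed to 48.8 ± 1.24 TPM in siCtrl and 70.3 ± 2.87 TPM in siNUDT5, with TUBB3, the most abundant, at 28.8 ± 2.92 and 40.0 ± 2.83 TPM. SOX2 (1.07), SYP (0.94) and SNAP25 (0.86) were higher and MAP2 (-0.51) was lower. For the endothelial and neural list the adjusted p was 0.211 by camera and 0.0139 by fry, each as higher. Of these lists 8 of 19 epithelial, 6 of 17 leukocyte and 6 of 17 endothelial and neural markers had a mean of at least 1 TPM in these cells.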

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

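The NUDT5 log2 change stayed past the threshold under each of the 16 settings fixed in advance, from -4.08 (pseudocount 0.1) to -2.79 (pseudocount 5). NUDT5 carries AAGACTT and so is absent where word-carrying genes are left out. None of the 107 other named genes changed direction under any of these 16 settings that tested it, and 67 passed wherever tested, with 90 of the 107 tested at a mean of at least 5 TPM. The groups did not overlap in any named gene. Only the scalings and leaving out mitochondrial genes could therefore have changed a direction, and the other settings do not test it. All of the 24 largest rises and falls passed in each of the 16 that tested them. The count of 1970 genes stayed between 1619 (mean of at least 5 TPM) and 2001 (pseudocount 5) under the other pseudocounts, filters, scalings and priors. It ranged from 764 (without siNUDT5 3) to 3804 (without siCtrl 2) when 1 library was left out, which also leaves fewer samples to estimate the spread. No gene of the 1970 that was still tested changed sign. The groups did not overlap in 1969 of the 1970, so for these leaving out 1 library could not change the sign. The cause of the higher count without siCtrl 2 was not tested. The count with at least a 2-fold change was 157, against 273 with a pseudocount of 0.1 and 58 with a pseudocount of 5, as a smaller pseudocount enlarges changes of low genes. It was 149 to 174 without single libraries, and 85 without genes carrying the 3' UTR words AAGACTT, AGACTTA or GATTAAC or lacking a searched 3' UTR. That alternative was chosen after seeing the data and also tests fewer genes (8806). That alternative left 1338 genes past the threshold and 7 lists, 6 of the 10 and the YAP and TAZ targets (camera adjusted p = 0.0317). The NF-kappaB (0.464), glycolysis (0.113) and immediate early lists (0.186) no longer passed, with fewer members tested and medians of -0.04, 0.14 and 0.31 against -0.08, 0.16 and 0.32, and the mitochondrial transcripts, with no 3' UTR searched, were not tested. No glycolysis or immediate early gene that rose was found to hold GATTAAC.

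The replicate number as a block gave 739 genes past the threshold, 733 of them among the 1970. Same-numbered libraries did not deviate together, with correlations of -0.43, -0.54 and -0.04 across genes, and none of the siCtrl libraries correlated best with its own number, so the numbers were not read as pairs.

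The count of lists past camera was 10. It was 9 to 14 under the other planned camera settings with all libraries, and 6 (without siCtrl 1) to 12 (without siCtrl 2) without single libraries. It was 0 with an estimated correlation, which was 0.108 for the integrated stress response and 0.637 for ribosomal proteins against the preset 0.01. For the interferon-stimulated list the estimate was -0.019, below the preset, and camera's adjusted p still went from 0.0123 to 0.459. A larger correlation between its members therefore cannot be what raised that p. The adjusted p with an estimated correlation is thus no measure of the effect of correlation alone. The integrated stress response, interferon-stimulated, homologous recombination and NRF2 lists passed in each of the 17 camera settings with the preset correlation and without the added alternative. Fry passed 14 lists, only 6 of them among the 10. It lost the homologous recombination, ribosomal protein, mitochondrial transcript and NF-kappaB lists and added 8, the p53, heat shock, SWI/SNF, Polycomb, TGF-beta, osteoblast, apoptosis and endothelial and neural lists. The 8 added were all called higher, and the lists lost were all lower by camera. Fry takes no account of the median of all genes, which was 0.05 without scaling. The 3 against 3 libraries allow 10 splits, too few for a share under 0.05, since 1 of the 10 splits is the real one. The real split gave 1970 genes, 157 of them at least 2-fold, and 10 lists. Each of the other splits gave 0 genes but 2 to 6 lists, so camera with the preset correlation also passed lists in mixed groups. A mixed split puts the group difference into the spread, which works against calling genes. Depth limits low genes most, since siCtrl 2 had 64.1% of the depth of siCtrl 1.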

Other observations

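The tests of gene families, 3' UTR words and siRNA seeds, and the use of siCtrl 2 as an explanation, were chosen after the data were seen, while the integrated stress response list and leaving out each library were fixed before. Among 154 families of at least 10 tested genes, grouped by the letters of their symbols, 6 passed camera, with protocadherin beta, semaphorin and SOX genes higher and RPL, ZNF and ATF genes lower. All 10 PCDHB genes had log2 changes above 0 and 4 passed the gene-wise threshold, among them PCDHB8 (0.84) and PCDHB16 (0.72). The family's median was 0.40 and camera gave adjusted p = 0.0172. These paralogs are similar in sequence, and reads shared between them are a limit. Of 15 semaphorin genes, which encode guidance cues, 7 rose and none fell, with SEMA4C at 0.88 and SEMA7A at 0.84 beside SEMA6B (camera adjusted p = 0.0483). Of 10 SOX transcription factor genes 4 rose and none fell, with SOX9 at 0.79, SOX5 at 0.64 and SOX6 at 0.51 beside SOX2 (camera adjusted p = 0.0483, and 0.0522 without siCtrl 2). The 48 RPL genes, which encode ribosomal proteins, the 426 ZNF genes and the 10 ATF genes had medians of -0.10, -0.05 and -0.30, each with camera adjusted p = 0.0172. Past the gene-wise threshold 1 RPL gene and 2 ATF genes fell and none rose. For ZNF, with 11 rises and 13 falls, the camera adjusted p was 0.286 without siCtrl 2. The 6 medians kept their sign under each scaling, though that of RPL was -0.05 with quantile normalization against -0.10. The camera adjusted p was 0.991 for each family with an estimated correlation.

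Genes with AAGACTT in the 3' UTR were lower in siNUDT5. Their z was -13.0, the lowest of 16354 words, and it lay between -12.7 and -10.4 in the 9 pairs of a siNUDT5 with a siCtrl library, against -3.03 to 3.57 in the 6 pairs within groups. Base composition of the 3' UTR is argued against, since in held-out genes, not used to pick the word, distinct words of the same bases had a mean median z of -0.29 over both parts and none was below -3.68, against -8.37 and -10.0 for the word, and so is the shallower library siCtrl 2, without which z was -12.3. A candidate explanation is the seed of the NUDT5 siRNA. Genes with the 8-base site AAGACTTA differed from those with AAGACTT not followed by A by -0.085 (standard error 0.0191) in adjusted log2 change. Both parts picked the same word, so these genes were all 2035 carriers. AGACTTA already ranked 2 among the lower words in the scan of all genes, so the 8-base comparison is not independent of the scan. Of 6 NUDT5 coding transcripts 3 held AAGACTT, as did 10.5% of 1548 genes of similar length. The siRNA sequences were not used here and a change in a cellular microRNA was not tested, so both stay open.

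Genes with GATTAAC in the 3' UTR were higher in siNUDT5. Their z was 13.7, the highest of all words, and 9.79 to 13.9 in the 9 pairs between groups, against -3.17 to 3.54 within groups. Base composition of the 3' UTR is argued against, since in held-out genes distinct words of the same bases had a mean median z of -0.34 over both parts and none was above 3.22, against 10.2 and 9.11 for the word, and so is the shallower library siCtrl 2, without which z was 14.4. Repression by the seed of the control siRNA in the siCtrl libraries stays open. Genes with the 8-base site GATTAACA differed from those with GATTAAC not followed by A by 0.049 (standard error 0.0290), which is within 2 standard errors of 0. Here too both parts picked the same word, so these genes were all 740 carriers. None of the NUDT5 coding transcripts held the word, and a cellular microRNA stays open here too. Another word, ATAATAC, ranked 2 among the higher ones, with a z of 8.24 over 1376 carriers. The highest z of any word was 3.36 in 1 permutation of the genes, which breaks links between genes. Pairs within groups already reached 3.57 for AAGACTT and 3.54 for GATTAAC, so the permuted value is a low bar. It was not among the words whose carriers were left out, and its cause was not tested.

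Among genes that passed, 257 of the 615 lower ones with a searched 3' UTR held AAGACTT or AGACTTA (41.8%, against 22.4% of all searched genes), and 169 of 1321 higher ones held GATTAAC (12.8% against 6.21%). The words were picked on these same log2 changes, so such an excess follows from the pick and is no separate evidence.

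The integrated stress response genes were lower in siNUDT5 as a list by camera with the preset correlation, and 15 of 29 members fell and 1 rose. With an estimated correlation camera's adjusted p was 0.459. The down-associated words in the members' own 3' UTRs are argued against, since the 25 members without AAGACTT or AGACTTA had a median log2 change of -0.34 and 14 of the 15 falls were among them. The shallower library siCtrl 2 is argued against too, since the median was -0.38 without it. Loss of NUDT5, the biological explanation the design gives, may lie behind the fall, but the comparison holds a single siRNA condition per group, so effects of either siRNA on other genes upstream of ATF4 stay open and were not tested.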
